A study of Mus musculus with 6 samples.

How the data were processed

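RNA was measured in naive CD4+ T cells sorted from the spleens of C57BL/6J mice aged 1 year, in 3 control and 3 Creld1cKO samples. Per the labels' protocols, 10 ng of RNA per sample went into libraries made with the TruSeq RNA version 2 kit, which were read as 75 bp single-end reads on a HiSeq2000. The submitters' processing notes name the genome build mm10 and the tools CASAVA 1.8, HISAT2 2.1.0, SAMtools 1.4, Partek 6.6 and DESeq2, without their roles or order. The counting tool, its use of strand, the annotation release, any filter on low genes and the exact transformation are not given in the sources used here.

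The authors deposited 1 table of normalized values on a log2 scale, with 1 column per sample and 22586 genes, and 0 columns of values were left unused. That the values are logarithms to base 2 was read from the values: they ran from -0.18 to 20.24, and 2 raised to each value summed to between 23252098 and 29305370 per library, the size of a read total. The spread over the 6 libraries shrank at low levels, with a median SD of 0.03 for genes with a mean under 2 and 0.17 for genes between 8 and 10. A set of 9 low genes shared identical values in all 6 libraries. This is the shape of a regularized logarithm, which draws low genes towards their mean, so a log2 difference understates the change of a low gene. Whole reads were not recovered from such values, the depth of each sample is unknown, and no count model was run. The total of 2 raised to the values is not a depth, since the authors had already scaled the libraries.

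The comparison had been planned on log2(value + 1) of linear normalized values. Because the deposited values already were on a log2 scale, they were used as they stand, and a gene was tested when the mean of 2 raised to its values was at least 10. This left 15252 genes. Gene identifiers were matched without their version to GENCODE M21, an annotation of mm10, for 22547 genes (99.8%), and the chromosome was the same in both for 22547 of them. Positions and exonic lengths are from that annotation. Exonic length counts each annotated exon base of a gene over all its transcripts, so it can exceed the length of any single transcript. Differences are Creld1cKO minus control, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Confidence intervals are at 95%. No batch is given in the labels and no covariate entered the fit. Mean values are given with the SD over 3 samples. The mouse identifier is 6 for every sample, and the labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

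A set of 27 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings. The lists cover naive and quiescence genes, activation and memory, exhaustion and age-associated genes, TCR signalling, TCR-induced early genes, calcineurin-NFAT, Wnt pathway components, Wnt beta-catenin targets, apoptosis promoting and restraining genes, cell cycle, the unfolded protein response and ER chaperones, interferon-stimulated genes, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis, and stress and dissociation immediate-early genes. Further lists hold markers of regulatory T cells, B cells, plasma cells, CD8 T cells, NK cells and gamma-delta T cells, myeloid and dendritic cells, erythroid cells and platelets, then sex-linked genes and the genes of the sorting gate. The lists with at least 5 tested members, other than the sex-linked and gate genes, were tested with camera from limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 24 lists. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were alternatives.

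The rule for named genes took Creld1, then in each direction the 12 genes with the largest change among those past the adjusted threshold with separated groups, filled up by the smallest p where fewer passed. It left out gene models without a name of their own, receptor variable segments, Xist and Y-linked genes. From each list it took up to 4 members past the threshold, or else the 2 with the smallest p. Some genes that the rule names are not reported here. The 1 gene past the threshold, Gm33707, falls outside the rule and was named after its value was seen. Similarity of its transcript to other GENCODE transcripts was searched with BLAST 2.17.0.

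The fit was tested on simulated values for 15252 genes with the means and residual spreads of this comparison. Of 50 genes changed by each size, it recovered 36% at a log2 change of 0.5, 84% at 1, 100% at 2 and 98% at 3, with 9 false calls. A simulated list of 40 genes shifted by -0.3 was called, and 0 of 100 unshifted lists were. These simulated genes varied independently of each other, which real genes of a list do not. The other settings fixed beforehand were pseudocounts of 0.5 and 10, no filter and a minimum of 100, trimmed-mean and quantile scaling, robust limma, array weights, a threshold of 0.1, a covariate from B cell, myeloid and erythroid markers, and each sample left out in turn. A pseudocount of 1, a correction for exonic length by local regression (span 0.5) and a preset correlation of 0.05 were added after seeing the data, as was leaving out each sample for the groups of the closing section and for the genes passing over their list alone.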

Results

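Per the labels, CD4+ T cells of Creld1cKO mice are deficient in Creld1, which encodes a membrane protein of the endoplasmic reticulum, and the series asks how gene expression in naive CD4+ T cells of such mice differs from that of controls at 1 year of age. Naive CD4+ T cells, helper T cells that have not yet responded to antigen, had been sorted from spleen by surface CD3 and CD4, the absence of CD25 and CD44 and a further marker of naive cells, and were processed without treatment. There were 3 control and 3 Creld1cKO samples. The deposited values are normalized and on a log2 scale, so the depth of the libraries is unknown and the number of samples limits the precision. Correlations between libraries across the tested genes ran from 0.990 to 0.997 over 15 pairs, and no pair held identical values. The first principal component took 42.9% of the variance, with control 3 at -30.1, control 1 at -6.09, control 2 at 0.60 and the Creld1cKO libraries at 4.97, 11.3 and 19.3. The second component took 25.1% and set control 2 apart, at 26.6 against -7.44 to -3.46 for the other libraries.

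Creld1 itself was lower in all 3 Creld1cKO samples than in any control, by a small amount that did not pass the test. The gene (ENSMUSG00000030284.11; mm10 chromosome 6, 113483297 to 113493343, plus strand) measured 6.12 ± 0.05 in controls (SD, n = 3) and 5.92 ± 0.03 in Creld1cKO samples (SD, n = 3). The difference of -0.21 (SE 0.11, 95% interval -0.44 to 0.03), a change of -13.2%, had an adjusted p of 0.41 in limma with Benjamini-Hochberg adjustment. With a mean of 6.02 over the 6 libraries, Creld1 was a low gene. Such values draw low genes towards their mean, so -13.2% may understate the change. The exact permutation test, two-sided, gave p = 0.1, the smallest that 3 samples against 3 allow. Of 1157 genes within 0.5 of its level, 280 (24.2%) had a larger absolute difference. Values per gene do not show which exons were read, so they do not check a deletion of part of the gene.

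Gm33707 rose in Creld1cKO cells. This processed pseudogene (ENSMUSG00000102298.1; mm10 chromosome 3, 60769887 to 60770455, minus strand) measured 5.97 ± 0.02 in controls and 8.65 ± 0.18 in Creld1cKO samples (SD, n = 3 each), a log2 difference of 2.68 (SE 0.13, adjusted p = 5.43e-05 in limma with Benjamini-Hochberg adjustment), higher in 3 of 3 samples. The control SD of 0.02 lay below the median SD of 0.12 over 6 libraries for genes with a mean between 4 and 6. Such values draw low genes towards their mean, so the reads behind the control level are unknown and 2.68 may understate the change. The transcript of Gm33707 was 89.5% identical over 573 bases to that of Eno1, a glycolytic enolase, and similar to further Eno1 pseudogenes. Reads may therefore have been split among these copies, and the level of Gm33707 is uncertain. It was the only 1 of 15252 tested genes past the adjusted threshold, and 0 genes fell past it. At an unadjusted p under 0.05 limma gave 2122 genes, 1165 higher and 957 lower, where 762.6 would be expected by chance. The groups did not overlap for 3195 genes (20.9%), where chance gives 10%. Genes that move together make such counts vary widely. Splits of the 6 samples that mixed the genotypes gave up to 1535 genes at an unadjusted p under 0.05 in limma. An excess over the chance figure does not by itself show an effect of genotype.

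**Figure D1:**
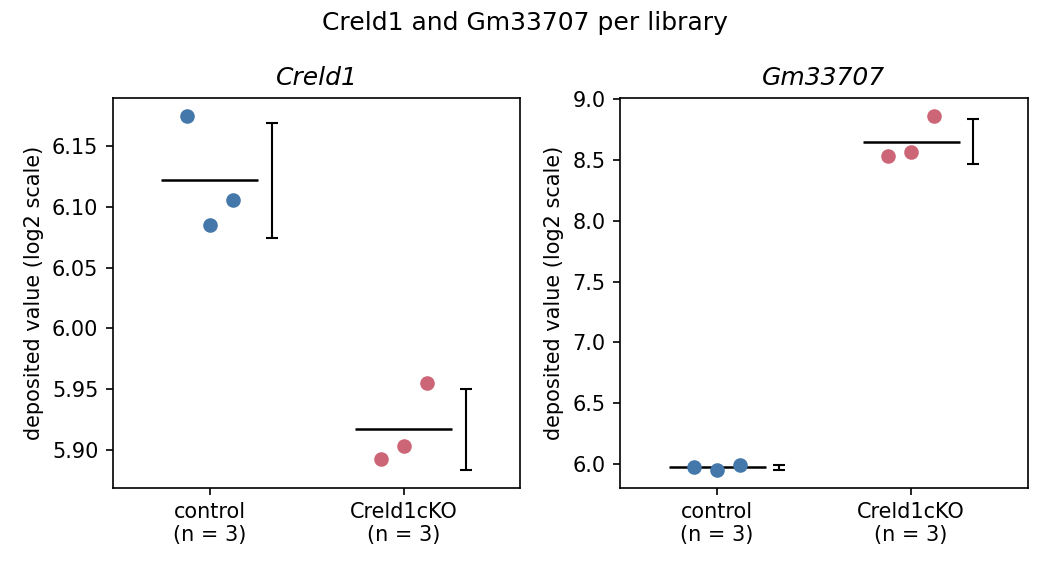
Deposited log2-scale values of Creld1 (left) and Gm33707 (right) in each library, with control samples in blue and Creld1cKO samples in red, horizontal lines for group means and bars for the SD (n = 3); the axes do not start at 0. Creld1 lies at 6.12 and 5.92 on average, and Gm33707 at 5.97 and 8.65.

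The named genes with the smallest p did not pass the adjusted threshold and are given as values, each with an adjusted p of 0.317 in limma with Benjamini-Hochberg adjustment and separated groups. Among those higher in Creld1cKO samples, Nsun5, a methyltransferase of ribosomal RNA, measured 8.87 ± 0.22 in controls and 9.55 ± 0.03 in Creld1cKO samples (SD, n = 3 each). The DNA repair gene Ercc6 measured 9.92 ± 0.25 and 10.65 ± 0.15, and the ubiquitin ligase gene March7 measured 11.32 ± 0.05 and 11.81 ± 0.08. Nfat5, a transcription factor of the response to hypertonicity, measured 11.34 ± 0.18 and 11.89 ± 0.05. The others were Rbm33, Nktr, Pvt1, Zfp871, Olfr539, Yeats2, Herc4 and Fnbp4, with differences from 0.50 for Rbm33 to 0.77 for Olfr539. Among those lower, Rn7sk, the 7SK RNA that restrains transcription elongation, measured 7.91 ± 0.42 in controls and 6.65 ± 0.12 in Creld1cKO samples. The translation initiation factor gene Eif1ax measured 10.94 ± 0.29 and 10.17 ± 0.15, and Nfe2l1, a transcription factor of proteasome genes, measured 11.51 ± 0.05 and 11.03 ± 0.16. Mir6236 and AA474408 had the largest differences, -3.27 and -3.09, with a control SD of 1.90 and 1.84 against 0.09 and 0.19 in Creld1cKO samples. Both were highest in control 2, the library set apart on the second component, at 12.88 and 13.74. Control 1 had 10.53 and 11.30, and control 3 had 9.11 and 10.13. Tmem254c, Slc16a5, Snd1, Ndufa2, Etfb, Sfr1 and Tomm7 differed by -0.62 for Ndufa2 to -0.42 for Slc16a5. The genes named as higher tended to be longer than those named as lower. Their exonic lengths ran from 4317 bases (Nsun5) to 21283 (Nktr), against 123 (Mir6236) to 9757 (Snd1). Among protein-coding genes outside the lists, the median difference was -0.06 for the 3711 shortest and 0.06 for the 3711 longest. The differences given here are not corrected for exonic length. Like Rn7sk, some other noncoding RNAs, chosen after their values were seen, were lower without passing. Rn7s1 and Rn7s2 differed by -1.71 each, mt-Rnr1 by -0.86 and mt-Rnr2, with overlapping groups, by -0.80. Of the small nucleolar and Cajal body RNAs, 25 of 38 were lower. Whether the libraries differed in how such RNAs were captured was not tested.

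Genes of protein synthesis and energy metabolism were lower as groups in Creld1cKO cells. All 74 tested cytosolic ribosomal protein genes were lower, with a median log2 difference of -0.58, as were 37 of 39 genes of oxidative phosphorylation (median -0.27) and 15 of 19 genes of glycolysis (median -0.28). These 3 lists fell by camera at its preset correlation, with adjusted p = 8.73e-32, 4.84e-13 and 7.27e-05, and no list rose. With an estimated correlation each had an adjusted p of 0.816, and with fry 0.526, so none of the 3 calls held with either. Over all genes 0 members of these lists passed, and adjusted over the list alone 66 ribosomal protein genes did and 0 of the other 2 lists. Over the list alone 0 ribosomal protein genes passed without control 1, control 3, Creld1cKO 1 or Creld1cKO 3, against 62 without Creld1cKO 2 and 71 without control 2. In oxidative phosphorylation 9 passed without control 1 and 19 without control 2, and in glycolysis 1 and 11. Rpl37 measured 14.34 ± 0.32 in controls and 13.67 ± 0.22 in Creld1cKO samples, and Rpl11 measured 14.37 ± 0.31 and 13.69 ± 0.24 (SD, n = 3 each). In oxidative phosphorylation, the complex I subunit genes Ndufa2 and Ndufb10 differed by -0.62 and -0.47, and in glycolysis the glucose transporter gene Slc2a1 and the kinase gene Pgk1 by -0.42 and -0.46. Ribosomal protein genes and Eno1 have many processed pseudogenes, so single values among them are uncertain. The ribosomal protein genes lay 0.66 above their 6-library mean in control 3, the library set apart on the first component, 0.19 above in control 1 and 0.01 above in control 2, and at -0.25, -0.10 and -0.52 in the Creld1cKO libraries. Without control 3 the medians were -0.39, -0.17 and -0.17 for ribosomal proteins, oxidative phosphorylation and glycolysis. Under quantile scaling the ribosomal median was -0.25, and the 3 lists were called in both settings at the preset correlation. Such repeated calls add little support, since the correlation within these lists was estimated at 0.82, 0.58 and 0.41, against the preset 0.01. At that preset 8 of the 10 splits of the 6 samples into 3 and 3, the real one included, gave at least 3 called lists. Across 11133 protein-coding genes outside the lists, which are not independent replicates, the Spearman correlation of exonic length with deviation from the mean was -0.02, -0.13 and -0.28 in the controls and 0.21, 0.12 and 0.27 in the Creld1cKO libraries. With length correction, chosen after seeing the data, the medians were -0.50, -0.18 and -0.30, called at the preset correlation.

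**Figure D2:**
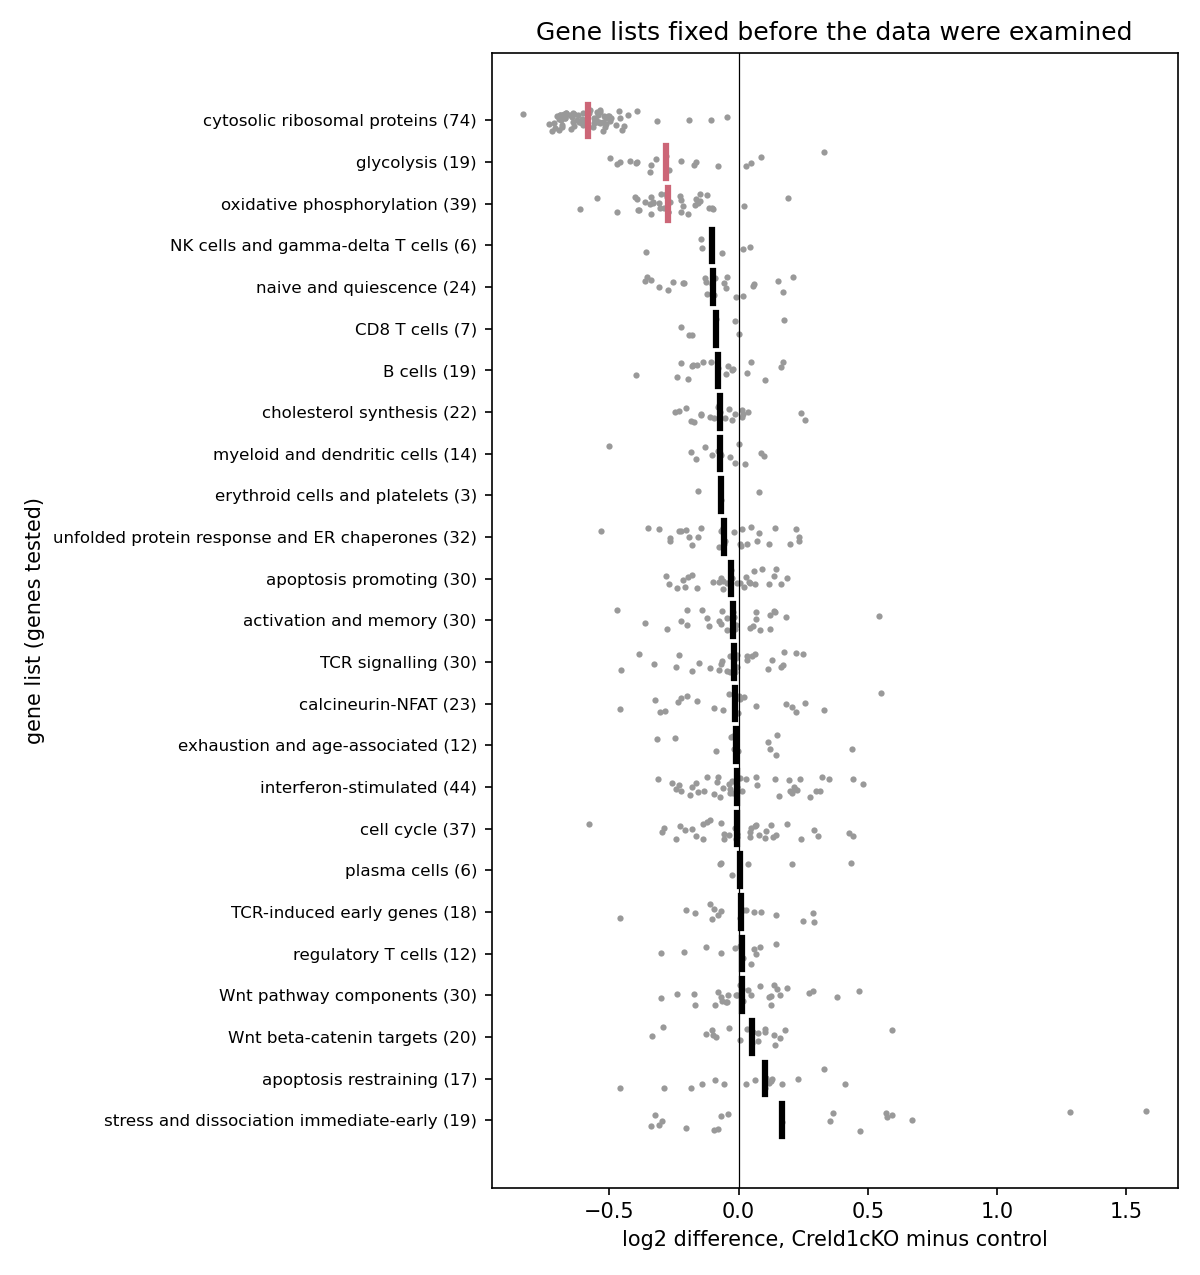
Log2 differences (Creld1cKO minus control, n = 3 each) of the tested members of each gene list, 1 grey point per gene, with a vertical line at the list median, red where camera at its preset correlation gave an adjusted p under 0.05. The ribosomal protein, glycolysis and oxidative phosphorylation medians lie at -0.58, -0.28 and -0.27; erythroid cells and platelets (3 genes) were not tested as a list.

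The stress and dissociation immediate-early list was not called (adjusted p = 0.11, camera; 0.816 with an estimated correlation), with 10 of 19 members higher, a median of 0.17 and 0 members past the threshold over all genes. It was called higher without control 3 (adjusted p = 0.00292, median 0.41), without Creld1cKO 1 (0.00427, median 0.17), under quantile scaling (0.0208) and with array weights (0.0343, median 0.31), and in no other setting. Adjusted over the list alone 6 members passed, and these were Jun, Junb, Dusp1, Nfkbiz, Hspa1a and Hspa1b, of which Dusp1, Nfkbiz and Hspa1b were named after their values were seen. Leaving out 1 library left 2 (without Creld1cKO 1) to 7 (without control 2) members past that threshold, with 3 without control 1 or control 3 and 4 without Creld1cKO 3. The transcription factor gene Junb measured 12.02 ± 0.16 in controls and 12.49 ± 0.16 in Creld1cKO samples, and the heat shock gene Hspa1a measured 6.16 ± 0.54 and 7.44 ± 0.67 (SD, n = 3 each). The groups overlapped for Hspa1a, with control 1 at 6.78 and Creld1cKO 1 at 6.73. The members Hspa8, Hsp90aa1 and Dnajb1, also chosen after their values were seen, were lower by point estimate, at -0.31, -0.29 and -0.32.

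**Figure D3:**
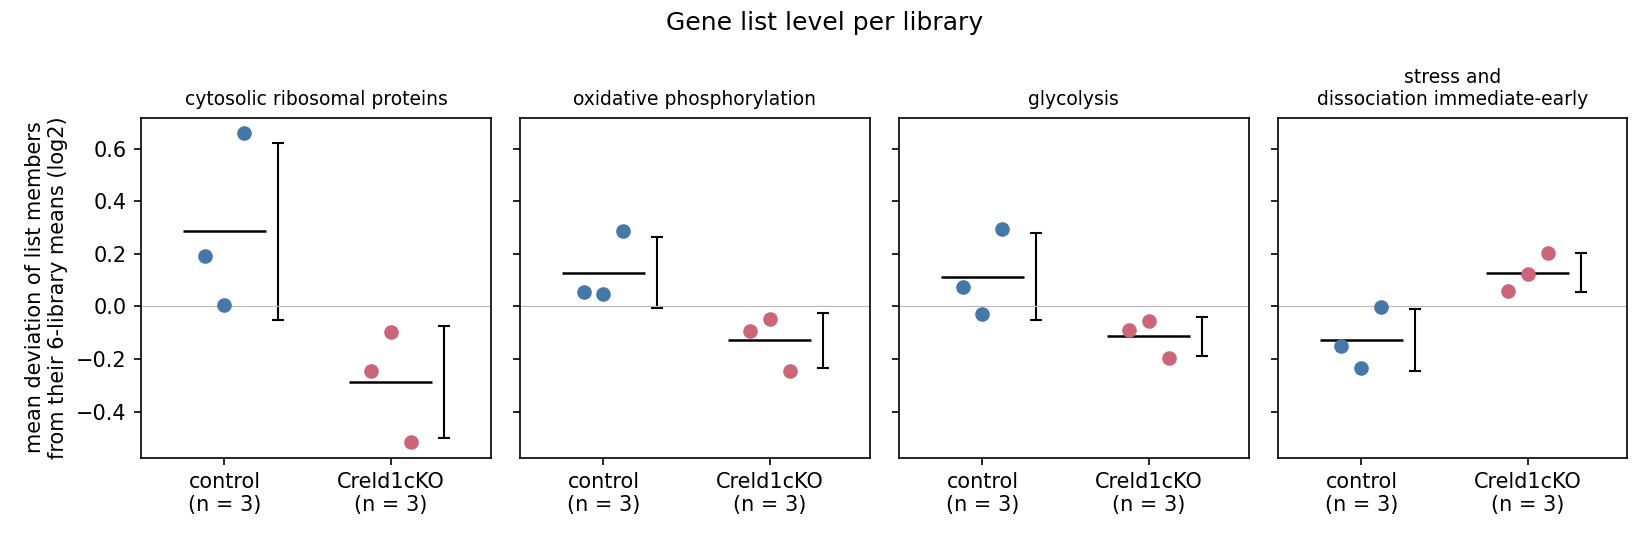
Mean deviation of each list's members from their own 6-library mean, on the log2 scale, per library, with group means as lines and bars for the SD (n = 3). Ribosomal protein genes stand at 0.19, 0.01 and 0.66 in the controls and at -0.25, -0.10 and -0.52 in the Creld1cKO libraries.

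Lists of T cell identity and signalling were not called. In the naive and quiescence list 18 of 24 genes were lower (median -0.10, adjusted p = 0.11, camera), including the naive T cell gene Dapl1 at -0.36 and Slfn2 at -0.35. The list was called lower with no filter (adjusted p = 0.0223), length correction (0.0103), array weights (0.00695), without control 2 (0.00493) and without Creld1cKO 2 (0.0266), all at the preset correlation; over all libraries its adjusted p was 0.889 with an estimated correlation and 0.701 with fry. It was not called in the other settings, up to 0.954 under quantile scaling, where the median was 0.02, and the median was -0.05 without control 3 and -0.06 without Creld1cKO 3. The activation and memory list (19 of 30 lower, median -0.02, adjusted p = 0.67) held Ahnak, a large scaffold protein gene that passed adjusted over the list alone at 0.54, and Lgals1 at -0.47. In the exhaustion and age-associated list, Tox and Nt5e differed by -0.25 and 0.44, and the median (-0.01) and mean (0.02) of its 12 genes differed in sign (adjusted p = 0.961). TCR signalling genes had a median of -0.02 (19 of 30 lower, adjusted p = 0.587; 0.01 under quantile scaling), with the receptor chain genes Cd3g and Cd3d at -0.39 and -0.46. TCR-induced early genes had a median of 0.01 and a mean of -0.01 over 18 genes (adjusted p = 0.764, in the lower direction), with Egr2 at -0.46 and Tnfaip3 at 0.29; the median became negative, at -0.0047, under quantile scaling. In the calcineurin-NFAT list, 13 of 23 genes were lower (median -0.01, adjusted p = 0.612), with the calmodulin gene Calm3 at -0.46. Its member Nfat5, the transcription factor of the response to hypertonicity, stood at 0.55 and passed adjusted over the list alone. This single member does not stand for the list. Over the list alone Ahnak passed with 1 library left out only without Creld1cKO 1, and Nfat5 did not pass without Creld1cKO 2 or Creld1cKO 3. Ahnak and Nfat5 are long, with 19938 and 18378 exonic bases, and these differences are not corrected for exonic length. The groups overlapped for Tox, Nt5e and Tnfaip3. Nt5e and Tnfaip3 stood at 0.18 and 0.11 without Creld1cKO 1, and Nt5e at 0.69 without Creld1cKO 3. Without control 3 Slfn2 stood at -0.22 and Lgals1 at -0.29.

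Wnt, survival and proliferation genes were not called either. Wnt pathway components (17 of 30 higher, median 0.02, adjusted p = 0.601) held Tnks at 0.38 and Csnk1e at 0.29. Their median turned to -0.0047 with array weights and -0.01 with length correction, where the test too pointed lower, and was 0.06 without control 1. Among Wnt beta-catenin targets (13 of 20 higher, median 0.05, adjusted p = 0.764), Jun stood at 0.59 and Cd44 at -0.29. Their median was 0.00045 without control 1 and 0.0060 with no filter, and the test pointed lower with no filter and with length correction. The apoptosis promoting list had a median of -0.03 (adjusted p = 0.535), with Ripk1 at -0.21 and Bnip3 at -0.28, and the apoptosis restraining list a median of 0.10 (adjusted p = 0.764), with Bag1 at -0.46 and Birc2 at 0.41. Cell cycle genes had a median of -0.01 over 37 genes (adjusted p = 0.837), with Mcm3 at -0.29 and Plk1 at 0.24. The unfolded protein response and ER chaperone list had a median of -0.06 over 32 genes (adjusted p = 0.201), with Ssr1 at -0.53 and Herpud1 at -0.23. The median was -0.02 without control 1, -0.04 without control 3 or Creld1cKO 3, and -0.09 with array weights. Interferon-stimulated genes had a median of -0.01 and a mean of 0.04 over 44 genes, which differ in sign (adjusted p = 0.652, in the higher direction), with Mx2 at 0.48 and Gbp4 at 0.44. Without Creld1cKO 2 the list was called higher at the preset correlation (adjusted p = 0.0138, median 0.07), and in the other settings its adjusted p ran from 0.0756 to 0.947 (adjusted p = 0.920 with an estimated correlation). Cholesterol synthesis genes had a median of -0.07 over 22 genes (adjusted p = 0.291), with Msmo1 at -0.23, and were called lower only without Creld1cKO 2 (adjusted p = 0.0281, median -0.13), against 0.0953 to 0.898 in the other settings, the highest with an estimated correlation. Without control 3 Tnks stood at 0.23, Bag1 at -0.30, Birc2 at 0.27 and Msmo1 at -0.13. None of these lists was called by fry or with an estimated correlation, where the smallest adjusted p was 0.526 and 0.816.

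Markers of other cell types gave no called list. The medians were 0.01 for regulatory T cells (mean -0.02, opposite in sign; Capg -0.30, Ikzf4 -0.21; adjusted p = 0.797), -0.08 for B cells (Ms4a1 0.17, H2-Eb1 -0.22; adjusted p = 0.311) and 0.0049 for plasma cells (Ighg1 0.43, Igkc 0.21; adjusted p = 0.764). The plasma cell and regulatory T cell medians became negative under quantile scaling, at -0.01 and -0.02. CD8 T cell markers had a median of -0.09 (Klrk1 0.18, Runx3 -0.18; adjusted p = 0.764), and markers of NK cells and gamma-delta T cells one of -0.10 (Prf1 -0.36, Gzma -0.14; adjusted p = 0.434). Markers of myeloid and dendritic cells had a median of -0.07 (adjusted p = 0.201, camera), with Cst3 at -0.50, which passed adjusted over the list alone, and Bst2 at -0.17. For erythroid cells and platelets only 3 genes were tested (median -0.07), among them Car2 at -0.16 and Itga2b at 0.08. Some of these markers were low, with 6-library means of 3.78 for Klrk1, 4.12 for Gzma, 4.35 for Ighg1 and 4.69 for Ms4a1. Others were not, such as Prf1 at 10.18 and Runx3 at 10.86. Differences of low genes are understated in such values, so uncalled lists do not show that the samples were equally pure. Over the list alone Cst3 passed with 1 library left out only without control 2. Without control 3 Capg stood at -0.16, H2-Eb1 at -0.12, Runx3 at -0.05, Prf1 at -0.18 and Bst2 at -0.08, and without Creld1cKO 3 Capg at -0.14 and Ighg1 at 0.66. Leaving out 1 library gave Ikzf4 from -0.36 to -0.08, Igkc from -0.13 to 0.52, Gzma from -0.22 to -0.07, Car2 from -0.26 to -0.01 and Itga2b from 0.01 to 0.19. Leaving out 1 library turned the sign of the median of apoptosis restraining genes (-0.02 without Creld1cKO 1) and of CD8 T cell markers (0.02 without control 3, and -0.22 without control 2 or Creld1cKO 1). It also turned, in at least 1 case each, the medians of the activation and memory, exhaustion, TCR-induced early, calcineurin-NFAT, apoptosis promoting, cell cycle, interferon, regulatory T cell and plasma cell lists. With array weights the medians of the activation and memory, exhaustion, TCR-induced early, cell cycle, interferon and regulatory T cell lists turned, and with length correction those of the exhaustion, cell cycle, interferon and regulatory T cell lists. A minimum of 100 turned those of the TCR-induced early and regulatory T cell lists, and no filter that of NK and gamma-delta T cells, to 0.02. Each list that was not called had a median that moved by over 1.5 times in at least 1 setting.

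Of the genes of the sorting gate, Cd44 measured 9.79 ± 0.12 in controls and 9.50 ± 0.17 in Creld1cKO samples, Il2ra (CD25) 5.77 ± 0.05 and 5.81 ± 0.04, and Cd3e 13.18 ± 0.20 and 13.17 ± 0.11 (SD, n = 3 each). Cd4 measured 14.73 ± 0.20 and 14.59 ± 0.03; the order of the groups for Cd4 and Cd3e turned under quantile scaling. Xist stood between 1.44 and 1.56 in the 6 libraries. The Y-linked genes Ddx3y and Uty, which passed adjusted over the list alone, measured 10.95 ± 0.43 and 11.64 ± 0.15, and 9.04 ± 0.30 and 9.50 ± 0.03, in controls and Creld1cKO samples. Kdm5d measured 10.66 ± 0.55 and 11.11 ± 0.13 and Eif2s3y 10.60 ± 0.38 and 10.57 ± 0.11. Control 3, the library set apart on the first component, was the lowest for each of these 4 genes, with Kdm5d at 10.03 against 10.91 and 11.04 in the other controls and Ddx3y at 10.46 against 11.22 and 11.18. Without it the differences of Ddx3y, Uty and Kdm5d went from 0.68, 0.46 and 0.44 to 0.44, 0.30 and 0.13, and that of Cd4 from -0.14 to -0.03. Ddx3y passed over the list alone with any 1 library left out, and Uty did not without Creld1cKO 1 or Creld1cKO 2. Leaving out 1 library turned the sign of the differences of Eif2s3y (-0.20 to 0.18) and Cd3e (-0.12 to 0.055).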

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

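The planned count models on recovered reads were not run, because the deposited values are on a log2 scale and no whole reads were recovered. A pseudocount of 1, the length correction and a preset correlation of 0.05 were chosen after seeing the data. Gm33707 was called in all 18 settings that fitted it, at 2.50 to 2.87 (adjusted p from 5.24e-06 to 0.00245, limma). Creld1 was lower in all 17, at -0.25 to -0.18 (adjusted p from 0.184 to 0.809), and has no value at a minimum of 100. Array weights gave 14 genes (8 higher, 6 lower) and 5 lists, adding naive and quiescence (lower) and stress genes (higher), and the marker covariate 2 genes; the cause was not tested. Leaving out 1 library gave 1 to 2 genes, Rn7sk being added without control 3 and AC167420.1 without Creld1cKO 2, and 3 to 6 lists, the 6 without Creld1cKO 2, which added naive and cholesterol genes (lower) and interferon genes (higher). With an estimated correlation 0 lists were called, and with fry 0. Of 1349 values of named genes in other settings, 1330 kept their direction and side of the threshold, 7 passed it and 12 reversed. Quantile scaling gave Cd4 0.15 and Cd3e 0.024, array weights Eif2s3y 0.021 and the length correction Gzma 0.0022. Leaving out 1 library, Cd3e ran from -0.12 to 0.055, Eif2s3y from -0.20 to 0.18 and Igkc from -0.13 to 0.52; the cause was not tested. The unknown depth limits what the low genes show.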

Other observations

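The tests of exonic length, expression level and variation between libraries were chosen after the results were seen. So were the mitochondrial, proteasome, receptor segment, histone, chemokine and small nucleolar RNA groups and the single genes from Lars2 to Foxp3. All 13 messenger RNAs encoded by the mitochondrial genome had a lower mean in Creld1cKO samples, but as a group their libraries overlapped. Their median log2 difference was -0.48 (adjusted p = 1.09e-04, camera, and adjusted p = 0.455 with an estimated correlation). Mitochondrial ribosomal protein genes (70 of 78 lower, median -0.18) and proteasome subunit genes (38 of 39 lower, median -0.21) fell by the same test (adjusted p = 2.43e-09 for each), as did T cell receptor beta variable segments (21 of 23 lower, median -0.20, adjusted p = 4.1e-06) and alpha variable segments (72 of 103 lower, median -0.06, adjusted p = 0.00834). With an estimated correlation each of these groups too had an adjusted p of 0.455, and 0 of their members passed over all genes. Control 3, the library set apart on the first component, lay highest: proteasome genes stood at 0.05, -0.01 and 0.25 around their 6-library mean in the controls, mitochondrial ribosomal protein genes at -0.0048, 0.05 and 0.21, and beta segments at 0.04, 0.0088 and 0.22. Without it their medians were -0.13, -0.10 and -0.13, still called at the preset correlation, and that of the mitochondrial messenger RNAs was -0.27, against -0.80 without control 2. The alpha segments were not called without control 3 (adjusted p = 0.0812, camera, median -0.03) or Creld1cKO 3 (0.0708, median -0.04), and had a median of -0.10 without control 1. The mitochondrial messenger RNAs differed more within the controls than between the group means. They stood at 0.48, -0.48 and 0.68 around their 6-library mean in the controls, against -0.29, -0.17 and -0.23 in the Creld1cKO libraries. Control 2 thus lay below every Creld1cKO library. Histone genes, chemokines and their receptors, and small nucleolar and Cajal body RNAs were not called (adjusted p = 0.646, 0.407 and 0.298, camera). Without control 3, however, the small nucleolar and Cajal body RNAs were called lower (adjusted p = 0.047, camera, median -0.06). Over all libraries their adjusted p was 0.520 by camera with an estimated correlation.

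Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, stood at 13.70, 16.24 and 12.66 in the 3 controls. It stood at 11.38, 11.30 and 11.60 in the Creld1cKO libraries (adjusted p = 0.317, limma). Values per gene do not show which part of Lars2 was read, so they do not show a change of the synthetase messenger RNA itself. Mir6236 and AA474408 moved with Lars2, at 10.53, 12.88 and 9.11, and at 11.30, 13.74 and 10.13, in the same controls. In the Creld1cKO libraries they stood at 7.60, 7.46 and 7.64, and at 8.68, 8.42 and 8.80. The 3 differences are therefore not separate observations, and what the shared pattern reflects was not tested. Rn7s1 and Rn7s2, near-identical gene copies with identical values in every library, measured 8.15 ± 1.08 in controls and 6.44 ± 0.13 in Creld1cKO samples (SD, n = 3 each). In controls 1, 2 and 3 they stood at 8.15, 9.23 and 7.07, the same order as Lars2, Mir6236 and AA474408, so they may share that pattern. The proliferation marker Mki67 was at 7.71 in Creld1cKO 1 and between 6.11 and 6.66 in the other libraries, and Foxp3, the transcription factor of regulatory T cells, at 7.67 there and between 7.02 and 7.43 in the others.

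The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 1 called gene and the highest of the others also 1, with 3 splits giving as many, and 2122 against at most 1535 genes at an unadjusted p under 0.05. It gave 3 called lists and the highest of the others 10, with 8 of the splits giving as many. Splits with several times the real number of called lists may reflect a structure of the samples or a correlation within lists above the preset. These counts cannot tell the 2 apart, since only the preset was used for them. The correlation within lists was estimated well above the preset 0.01 for the called lists, at 0.82 for ribosomal proteins, 0.58 for oxidative phosphorylation and 0.41 for glycolysis, and with it the real split gave 0 called lists; the other splits were not run that way.

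At the preset correlation the ribosomal protein, oxidative phosphorylation and glycolysis lists were called lower in Creld1cKO cells (74 of 74, 37 of 39 and 15 of 19 genes lower, 0 passing over all genes; adjusted p = 0.816 for each list with an estimated correlation and 0.526 with fry), along an axis on which long and short genes also moved apart. Over 11133 protein-coding genes outside the lists, the Spearman correlation across genes (which are not independent replicates) of exonic length with deviation from the mean was -0.02, -0.13 and -0.28 in the controls and 0.21, 0.12 and 0.27 in the Creld1cKO libraries. Against 10000 random lists matched on exonic length, the medians of -0.58, -0.27 and -0.28 lay below the lower bounds of the central 95%. These bounds were -0.12, -0.13 and -0.10, which argues against a trend with exonic length as the whole cause. Exonic length can exceed that of the transcripts present, so a trend with transcript length itself was not tested. Correcting for exonic length left -0.50, -0.18 and -0.30, all still called at the preset correlation. The correction took away part of the oxidative phosphorylation shift. Against lists matched on expression level the bounds were -0.24, -0.10 and -0.13, which argues against a level trend as the whole cause for oxidative phosphorylation and glycolysis; few genes reach the level of the ribosomal proteins (311 to draw from, median gap 0.178), and quantile scaling brought their median to -0.25, still called at the preset correlation. What stays open is a trend with transcript length, and a share of the ribosomal difference that follows level. Variation between libraries, such as in RNA handling, also stays open. With 3 samples each it cannot be told apart from an effect of losing Creld1. Of the 10 splits, 1, the real one, gave a mean ribosomal difference as large as -0.57, and another reached 0.50 in size.

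Gm33707 was the gene that separated the genotypes most firmly, and its transcript resembles that of Eno1. Eno1 itself differed by -0.34 (95% interval -0.69 to 0.01), which argues against reads spilling over from a higher Eno1 level. A linked segment around the pseudogene was tested through its neighbours: of 32 tested genes within 5 Mb, 3 (9.38%) had an unadjusted p under 0.05 against 13.9% of the rest (Fisher's exact test, one-sided, p = 0.842), and the 3 went both ways, with Mbnl1 at 0.33, Dhx36 at 0.32 and Rap2b at -0.37. A segment with few regulatory variants, or a recombinase transgene inserted near the pseudogene, could still give such a rise. Neither can be told apart from an effect of losing Creld1, because the labels name no recombinase line and each of them could follow the genotype. Since Creld1 lies on chromosome 6 and Gm33707 on chromosome 3, neither would follow it through linkage to Creld1 itself.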
